A study of Homo sapiens with 8 samples.

How the data were processed

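RNA sequencing libraries of the human acute myeloid leukemia cell line MOLM13 were analysed in 4 groups of 2: control, IGF2BP2 knockdown, rescue and mutant rescue. Groups and replicate numbers were taken from the sample titles, in which the knockdown titles spell the gene name with letters transposed. Per the labels' protocols the cells were infected with virus, selected with puromycin if needed, and polyadenylated RNA was sequenced. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The mutation and the hairpin sequence are not given in the sources used here.

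One table of the whole series was used. Per the file headers it was written by the getDiffExpression.pl program of HOMER, run on a gene table with the 8 libraries in 4 groups and every group compared with every other. The submitters' processing notes name Trim Galore, kallisto, HOMER and GRCh38, with no role, order or version. The library columns hold log2 values that the authors normalized across the 8 libraries before they were deposited; values of low genes lie close together in all libraries, and the header states no option for this. The authors' log2 fold changes and p-values, raw and adjusted, are deposited beside them for each pair of groups, and the model behind the p-values is not given in the sources used here. The authors' adjusted p is 1 also for some genes with a small p. The table lists 35370 genes, of which 1 has no symbol, 10937 are at 0 in every library and 26 have a number in place of a symbol, as spreadsheets write dates. Counts are not used here, so the depth of each library is unknown and no counting error can be given. The precision of each value is that of 2 libraries per group. The share of the linear total held by the 10 highest genes lay between 3.74% and 7.30% per library.

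The design fixed before the data were examined foresaw counts or TPM. Since the values are on a log2 scale, limma (version 3.58.1 in R 4.3.3) was run on them as deposited, with no pseudocount. A fold change is on this scale, which understates changes of low genes where the authors' values were drawn together. The authors' deposited log2 changes were larger also for high genes such as LYZ in knockdown (2.25 against 1.92 here). Over genes called by the authors, the slope of library differences on their log2 changes was 0.47 to 0.66, by comparison. Genes were kept with a value of at least 1 ppm of a library's linear total in at least 2 libraries, which left 13030. All 8 libraries entered a single model of group means with 4 residual degrees of freedom and empirical Bayes moderation with a mean trend. The contrasts were knockdown minus control, rescue minus knockdown, mutant rescue minus knockdown and rescue minus mutant rescue. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. On data simulated for 13030 genes, the procedure recovered 34% of genes changed by 0.5 log2 and 94% of those changed by 1 for knockdown against control, 31% and 96% for rescue against knockdown, 40% and 97% for mutant rescue against knockdown, and 33% and 94% for rescue against mutant rescue. Unchanged genes made up 5.88%, 7.97%, 6.16% and 8.63% of the calls in that order. The simulated noise was independent between genes and equal in all groups. In the data the SD of the log2 difference between replicates was 0.148 in knockdown and 0.303 in mutant rescue. These shares therefore do not give the false calls of the real contrasts, least of all those with mutant rescue.

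Of 30 gene lists fixed before the data were examined, 27 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over lists within each contrast. They cover the genes of the series title, IGF2BP and m6A factors, arginine methyltransferases, glutamine, lipid, sterol and glucose metabolism, the leukemia stem cell score, the HOXA/MEIS1 program, monocyte and granule genes, MYC targets, cell cycle phases, p53 targets, apoptosis, interferon, NF-kB, immediate early, amino acid and protein stress responses, oxidative phosphorylation, RNA quality, and other cell types. Overlaps of calls were examined only between knockdown against control and rescue against mutant rescue, which share no library, with one-sided Fisher's exact tests. Of the symbols tested, 12119 (93.0%) are in GENCODE v29, from which the positions of the genes of the series title were taken.

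Genes were named by a rule fixed before the data were examined. It takes IGF2BP2, PRMT6 and MFSD2A, and, per contrast, the 10 called genes with the largest increase and the 10 with the largest decrease whose libraries do not overlap between the groups and whose higher group averages at least 5 ppm, without clone-type symbols. It adds up to 4 called members per list with the smallest adjusted p, or the member of highest mean where none is called, and the 10 oppositely called genes with the smallest larger adjusted p. Alternatives were limma without the trend, rescaling by the median ratio, no filter, a minimum of 5 ppm, only the libraries of the groups compared, the replicate number as a block, a change of at least 2-fold, and each library left out in turn, where the lone library of a group is assumed to vary like the other groups. The calls of the authors' deposited table, the counts of list members without each library, and the use of ppm in the filter were added after seeing the data. That table comes from the same 8 libraries, so sharing a direction with it is no independent check. Near-identical gene copies are not told apart by gene-level values. Levels of sex-linked transcripts, and some genes that the rule takes, are not reported here.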

Results

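Messenger RNA was sequenced from MOLM13, an established human acute myeloid leukemia cell line, in 4 groups of 2 libraries each. Control cells carried a wild-type genotype label, knockdown cells were labelled as depleted of IGF2BP2, and both rescue groups were labelled as given back IGF2BP2 or a mutant of it. IGF2BP2 encodes a protein that binds RNA carrying N6-methyladenosine, and the series title places the arginine methyltransferase gene PRMT6 and the lipid transporter gene MFSD2A on an axis with it. The labels do not describe the mutation, nor say whether control and knockdown cells received an empty vector. Effects of infection or selection on knockdown against control are therefore not excluded. Read depth is unknown, because the deposited values are on a log2 scale and normalized across the 8 libraries. Replicates differed least in knockdown, with an SD of the log2 difference across genes of 0.148, followed by control at 0.212, rescue at 0.232 and mutant rescue at 0.303. The first principal component held 41.2% of the variance, with the control libraries at one end and mutant rescue replicate 2 at the other, and the second, with 25.6%, ran from the rescue libraries (scores of 21.38 and 23.34) to mutant rescue replicate 2 (-21.48), with mutant rescue replicate 1 at -7.45.

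The level of IGF2BP2 in every library was examined first, as a check of the labels. IGF2BP2 (chromosome 3, 185643739 to 185825056, minus strand, GRCh38, protein coding) had a log2 value of 10.92 ± 0.04 (SD, n = 2) in control and 10.25 ± 0.01 in knockdown. On the scale of the library values the transcript was 1.59-fold lower in knockdown, a log2 change of -0.67 (SE 0.13) with an adjusted p of 0.0147. In the authors' deposited table, from the same 8 libraries, the log2 change was -0.87 (adjusted p = 1.15e-07). IGF2BP2 stood at 11.25 ± 0.16 in rescue and 10.86 ± 0.24 in mutant rescue, both above knockdown (adjusted p = 0.00324 and 0.0298). The difference of 0.39 (SE 0.13) between the rescue arms did not pass the test (adjusted p = 0.0839). The gene-level values do not part endogenous transcript from that of a rescue construct. In the fits that left out 1 library the log2 change in knockdown lay between -0.70 and -0.64. It passed in a fit of only the control and knockdown libraries (adjusted p = 0.00287). The knockdown call was lost without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2 in turn, with adjusted p = 0.0662, 0.0754, 0.119 and 0.123. The call of mutant rescue over knockdown was lost without either knockdown library (adjusted p = 0.164 and 0.191) and in a fit of only these groups (adjusted p = 0.0722), and rescue exceeded mutant rescue without mutant rescue replicate 1 (adjusted p = 0.0161).

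PRMT6 (chromosome 1, 107056679 to 107067636, plus strand, protein coding) was 2.30-fold lower in knockdown on the scale of the library values, at 8.14 ± 0.09 against 9.34 ± 0.06 (SD, n = 2), a log2 change of -1.20 (SE 0.11) with an adjusted p of 0.000936. PRMT6 rose by 0.62 (SE 0.11) in rescue over knockdown (adjusted p = 0.0157), to 8.76 ± 0.08. These log2 changes were -1.71 and 0.89 in the authors' deposited table (adjusted p = 4.23e-15 and 0.00143). With 1 library left out they lay between -1.265 and -1.143 and between 0.56 and 0.68. In mutant rescue PRMT6 averaged 8.49, a difference from knockdown of 0.36 (SE 0.11) that did not pass the test (adjusted p = 0.0648). The rescue arms differed by 0.26 (SE 0.11, adjusted p = 0.137), so a difference in PRMT6 between the intact and the mutant protein was not detected. The PRMT6 call in rescue over knockdown was lost without knockdown replicate 1, knockdown replicate 2, rescue replicate 1 and rescue replicate 2 in turn (adjusted p = 0.107, 0.209, 0.119 and 0.0648).

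MFSD2A (chromosome 1, 39955112 to 39969968, plus strand, protein coding) was 1.41-fold higher in knockdown on the scale of the library values, at 9.01 ± 0.06 against 8.52 ± 0.02 (SD, n = 2), a log2 change of 0.49 (SE 0.13) with an adjusted p of 0.0469. This log2 change was 0.64 in the authors' deposited table (adjusted p = 0.0103). With 1 library left out it lay between 0.45 and 0.53. MFSD2A passed the test neither in rescue over knockdown (-0.15, adjusted p = 0.610) nor in mutant rescue over knockdown (-0.28, adjusted p = 0.182), nor between the rescue arms (0.13, adjusted p = 0.527). The MFSD2A call in knockdown was lost without control replicate 1, control replicate 2, knockdown replicate 1, knockdown replicate 2, rescue replicate 1 and rescue replicate 2 in turn (adjusted p = 0.139, 0.162, 0.256, 0.201, 0.0508 and 0.0506), and with no filter on low values (adjusted p = 0.0609).

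**Figure D1:**
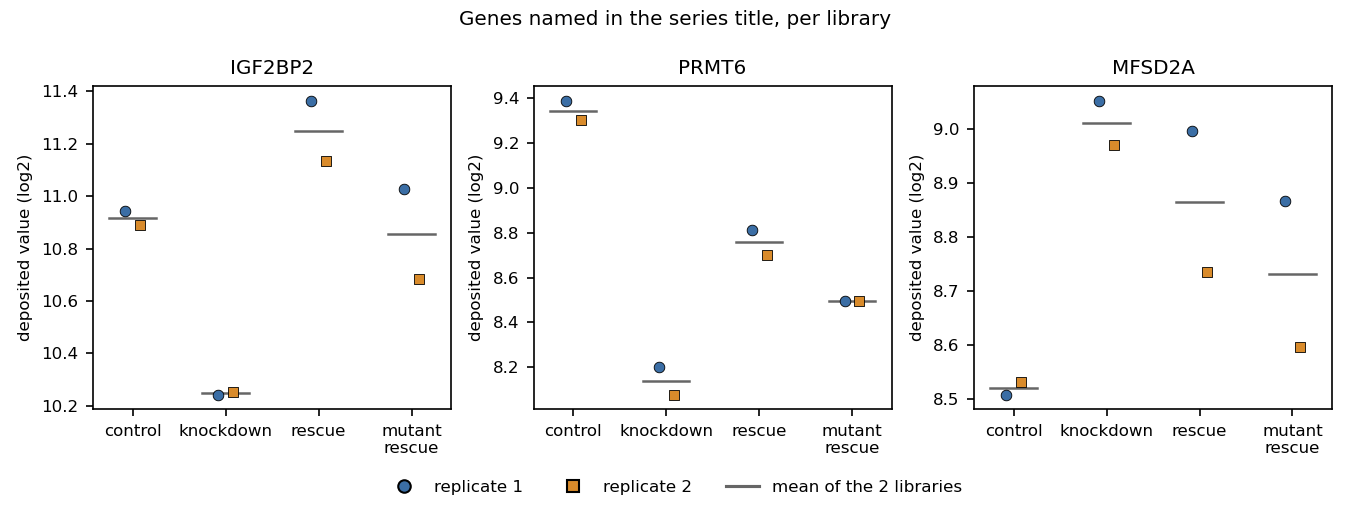
Deposited log2 values of IGF2BP2, PRMT6 and MFSD2A in each of the 8 libraries, by group; points are libraries and lines group means. IGF2BP2 and PRMT6 are lowest in both knockdown libraries, and PRMT6 lies at 8.49 in both mutant rescue libraries.

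Knockdown cells had lower levels of cell cycle genes and higher levels of monocyte genes than control cells. Of 47 S phase genes 32 fell and 0 rose, among them GINS2 (-1.24, SE 0.11), a subunit of the replicative helicase, CDCA7 (-0.91, SE 0.10) and the cyclin gene CCNE2 (-0.82, SE 0.10). Of 56 G2/M genes 30 fell and 0 rose, including the kinetochore genes CENPF (-0.97, SE 0.10) and CENPE (-0.97, SE 0.12), with UBE2C (-0.77, SE 0.11) and CCNB2 (-0.65, SE 0.10). Of 26 monocyte and macrophage genes 13 rose and 0 fell, led by the growth factor receptor gene CSF1R (1.27, SE 0.14), CD68 (0.85, SE 0.10), the lysozyme gene LYZ (1.92, SE 0.22) and VCAN (1.45, SE 0.17). When adjusted over the list alone, 38 S phase and 40 G2/M genes fell, and of the monocyte genes 15 rose and 1, IRF8 (-0.34, named after its value was seen), fell. The camera test called S phase (adjusted p = 6.01e-20), G2/M (4.38e-15) and monocyte genes (1.44e-07). The cell cycle calls held with an estimated correlation (adjusted p = 0.0168 for each), while monocyte genes had adjusted p = 0.0659 with an estimated correlation and 0.00195 with fry. Without control replicate 2, knockdown replicate 1 and knockdown replicate 2 in turn, the members called were 19, 5 and 5 for S phase and 12, 2 and 2 for G2/M, and without control replicate 1, knockdown replicate 1 and knockdown replicate 2 in turn 8, 7 and 5 for monocyte genes. Over the fits that left out 1 library the median log2 change lay between -0.58 and -0.54 for S phase, -0.46 and -0.42 for G2/M and 0.39 and 0.56 for monocyte genes.

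The 10 largest increases in knockdown were in PCSK5, SIGLEC6, OLR1, C3, DNASE2, CYBB, FCER2, LYZ, CD36 and PECAM1. PCSK5, a proprotein convertase gene, was 8.51-fold higher, a log2 change of 3.09 (SE 0.31) with an adjusted p of 0.00127. SIGLEC6 was 5.44-fold higher, and the scavenger receptor genes OLR1 and CD36 4.86-fold and 3.77-fold. CYBB, which encodes the catalytic subunit of the phagocyte NADPH oxidase, was 3.97-fold higher, and LYZ 3.79-fold. The 10 largest decreases were in SRI, PTPMT1, VAMP8, G3BP2, HENMT1, ALDH1A3, RASGRP2, MGST2, LMAN1 and FADD. SRI, which encodes the calcium-binding protein sorcin, was 4.52-fold lower, a log2 change of -2.18 (SE 0.12) with an adjusted p of 0.000188. The mitochondrial phosphatase gene PTPMT1 was 3.20-fold lower and the stress granule gene G3BP2 2.78-fold. Over all 13030 genes tested, 697 were called higher and 970 lower, and the total of 1667 was 1000, 492, 187 and 179 without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2 in turn. The larger share turned without control replicate 2 (255 higher, 237 lower), knockdown replicate 1 (116 and 71) and knockdown replicate 2 (101 and 78). The authors' deposited table listed 875 genes higher and 1740 lower. All 1568 genes called in both had the same direction, which the shared libraries all but fix. Cytosolic ribosomal protein genes had a median log2 change of -0.32 (camera adjusted p = 2.64e-08, and adjusted p = 0.677 with an estimated correlation) and mitochondrially encoded genes one of 0.20 (camera adjusted p = 0.136). These medians lay between -0.46 and -0.16 and between -0.02 and 0.41 in the fits that left out 1 library, so the sign of the latter turned.

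Further gene groups moved in knockdown. Of 40 MYC target and ribosome biogenesis genes 19 fell, including the chaperonin gene HSPD1 (-0.61, SE 0.09), the nucleolar gene NOLC1 (-0.57, SE 0.09) and MRTO4 (-0.57), and 1 rose, HK2 (0.77). In the HOXA/MEIS1 program of KMT2A-rearranged leukemia 5 of 18 genes fell, SATB1 (-0.93, SE 0.10), HOXA9 (-0.70, SE 0.09), MEF2C (-0.75), JMJD1C (-0.45) and PBX3 (-0.42). Of 10 arginine methyltransferase genes and partners 5 fell, PRMT6, CLNS1A (-0.99, SE 0.10), PRMT7 (-0.46), PRMT5 (-0.39) and PRMT1 (-0.42). Of 38 interferon-stimulated genes 12 rose, with OAS1 (1.02, SE 0.11) and OAS2 (0.87, SE 0.11) first. PBX3 and PRMT1 were named after their values were seen. Adjusted over the list alone, 24 MYC target, 6 HOXA/MEIS1 and 6 arginine methyltransferase genes fell and 16 interferon-stimulated genes rose. Camera called all 4 lists, at adjusted p = 5.37e-10, 0.000121, 0.000657 and 4.97e-07 in that order. None held with an estimated correlation, at adjusted p = 0.0651, 0.0659, 0.128 and 0.192. Fry called all 4, at adjusted p = 0.00115, 0.00212, 0.00110 and 0.00625. Without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2 in turn, the members called were 16, 4, 0 and 0 for MYC targets, 2, 3, 1 and 1 for HOXA/MEIS1, 4, 2, 2 and 2 for arginine methyltransferases and 6, 7, 2 and 2 for interferon-stimulated genes, and without either rescue library 3 arginine methyltransferases were called.

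**Figure D2:**
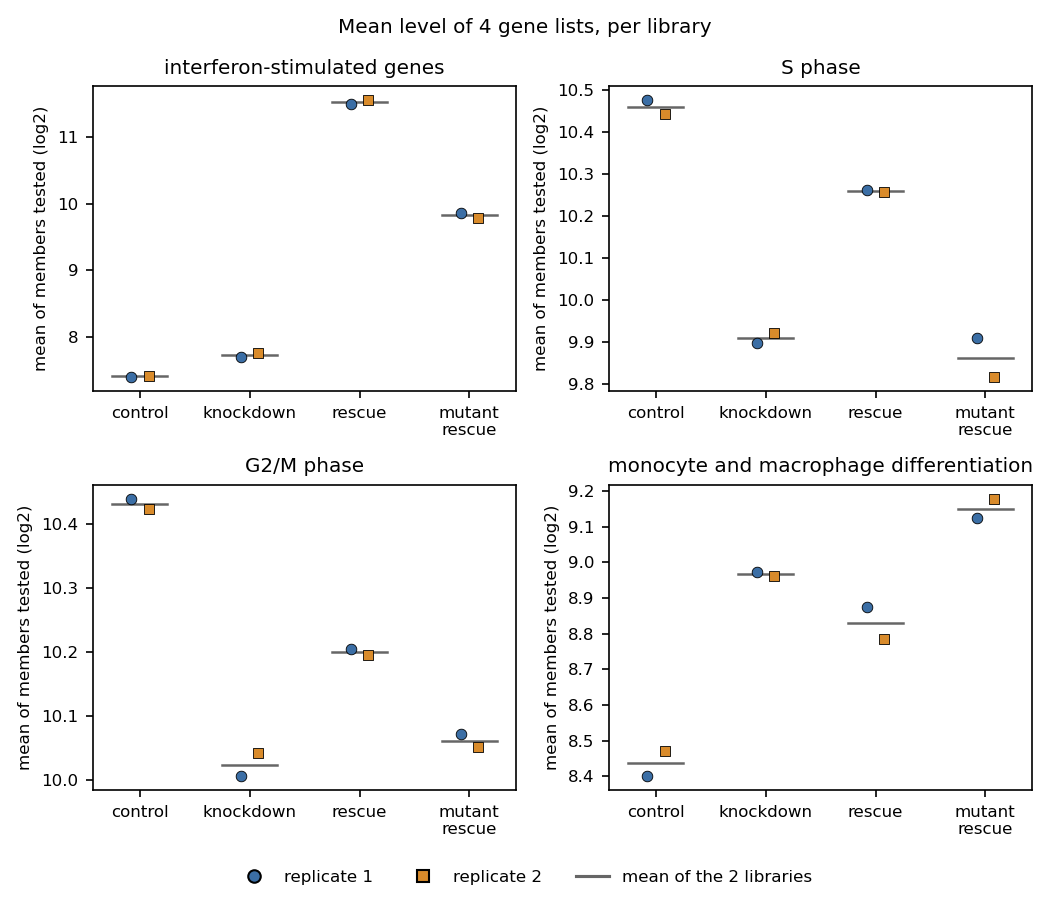
Mean deposited log2 value over the tested members of 4 gene lists in each of the 8 libraries, by group; points are libraries, lines group means, and each panel has its own axis. The interferon-stimulated genes average 7.40 and 7.43 in control and 11.49 and 11.55 in rescue.

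The comparison of rescue with knockdown asked which transcripts changed when IGF2BP2 was given back. All 38 interferon-stimulated genes rose, with a median log2 change of 3.66. The antiviral genes IFIT3 (6.61, SE 0.12), IFIT1 (6.54, SE 0.12) and IFI27 (6.52, SE 0.12) were 97.4-fold, 93.3-fold and 91.5-fold higher in rescue on the scale of the library values. The authors' deposited log2 changes for these genes were 7.98, 8.32 and 8.45. Their list averaged 7.40 and 7.43 in the control libraries and 11.49 and 11.55 in the rescue libraries. Of 47 S phase genes 13 rose and 0 fell, among them the helicase genes MCM5 (0.52, SE 0.09) and MCM7 (0.47, SE 0.08), and E2F1 (0.68, SE 0.12). Of 56 G2/M genes 3 rose, KIF20B (0.49), CENPF (0.50) and CDC20 (0.43). When adjusted over the list alone, 38 interferon-stimulated, 33 S phase and 10 G2/M genes rose. Camera called the 3 lists at adjusted p = 8.12e-89, 2.87e-14 and 2.35e-05. The first and second held with an estimated correlation (adjusted p = 0.0117 and 0.0224), while G2/M had adjusted p = 0.0893 with an estimated correlation. Without knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn, the members called were 0, 0, 1, 2, 22 and 22 for S phase and 0, 0, 0, 0, 7 and 7 for G2/M, while all 38 interferon-stimulated genes were called in every fit that left out 1 library.

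The other large increases were in IFITM1 (5.93), IFI6 (5.91), IFIT2 (5.76), the chemokine gene CXCL10 (5.73), IFITM3 (5.38), OAS3 (5.20) and IFI44L (5.13). The 10 largest decreases were in PCSK5, CPT1A, RAB2B, CLASP1, SIGLEC6, SORL1, TGFBR1, SNAI1, PLK2 and TP53INP1. PCSK5 changed by -1.65 (SE 0.31, adjusted p = 0.0212) and SIGLEC6 by -1.24 (SE 0.16), and both were higher in knockdown than in control. CPT1A, which encodes a carnitine palmitoyltransferase of mitochondrial fatty acid import, was 2.88-fold lower. Over all genes 420 were higher and 133 lower in rescue, and the total of 553 was 176, 176, 236, 243, 864 and 864 without knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn. The authors' deposited table had 918 higher and 401 lower, and all 530 genes called in both had the same direction. Cytosolic ribosomal protein genes had a median log2 change of -0.25 (camera adjusted p = 1.54e-07, and adjusted p = 0.549 with an estimated correlation) and mitochondrially encoded genes one of -0.32 (camera adjusted p = 0.000527, and adjusted p = 0.471 with an estimated correlation). Leaving out 1 library gave medians between -0.31 and -0.15 and between -0.39 and -0.27.

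Of 24 NF-kB and inflammatory genes 8 rose, with IL1RN (1.67, SE 0.10), NFKBIA (1.17, SE 0.11) and CCL3 (1.41, SE 0.14) after CXCL10, and 1 fell, IL1B (-0.38), named like TNFAIP2 after its value was seen. The IL1B call did not hold without knockdown replicate 1. Of 26 genes of the unfolded protein and heat shock response 7 rose, with the chaperone genes HSPA5 (0.96, SE 0.10) and DNAJA1 (0.75, SE 0.11) first, then PDIA4 (0.87) and CRELD2 (0.76). Adjusted over the list alone, 9 NF-kB genes rose and 2 fell, IL1B and TNFAIP2 (-0.36), and 14 unfolded protein genes rose. Camera called both lists (adjusted p = 0.000567 and 5.16e-05), with adjusted p = 0.0944 and 0.165 with an estimated correlation. The NF-kB list had a median log2 change of 0.13 against a mean of 0.57, with CXCL10 at 5.73. Whether these genes moved apart from the interferon-stimulated genes was not tested. Of 26 monocyte genes 3 fell, S100A8 (-0.73), ITGAX (-0.75) and VCAN (-0.78), or 4 adjusted over the list alone with S100A9 (-0.66, named after its value was seen), and camera did not call the list (adjusted p = 0.0798). Without knockdown replicate 1, knockdown replicate 2, rescue replicate 1 and rescue replicate 2 in turn, the members called were 5, 5, 5 and 5 for higher NF-kB genes, 1, 1, 1 and 4 for the unfolded protein response and 0, 0, 0 and 0 for monocyte genes.

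The same comparison for the mutant asked what changed when it was given to knockdown cells. Interferon-stimulated genes led again, with 37 of 38 higher and a median log2 change of 1.78. IFIT1 rose by 4.33 (SE 0.12), IFI6 by 4.28 (SE 0.19), IFI27 by 4.14 (SE 0.12) and IFIT3 by 4.01 (SE 0.12). S phase genes had no common direction, with E2F1 (1.09, SE 0.12) and CCNE2 (0.47) higher and HELLS (-0.79, SE 0.15) and RRM2 (-1.04, SE 0.26) lower among 47. Of 26 monocyte genes 3 were higher, LYZ (1.09, SE 0.22), CST3 (0.53) and CD14 (0.38). When adjusted over the list alone, 37 interferon-stimulated and 3 monocyte genes rose, and 2 S phase genes rose and 2 fell. Camera called the interferon-stimulated list (adjusted p = 2.41e-42, and adjusted p = 0.0497 with an estimated correlation), not S phase (0.555) or monocyte genes (0.140). Without knockdown replicate 1, knockdown replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn, the members called were 1, 1, 2 and 1 for higher and 0, 0, 6 and 1 for lower S phase genes and 0, 0, 4 and 0 for monocyte genes, and without either rescue library 1 S phase gene was lower. Interferon-stimulated genes called stayed between 27 and 37 in the fits that left out 1 library, and CCNE2 and CD14 did not pass in the authors' deposited table.

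The other large increases in mutant rescue were in IFIT2 (3.62), OAS2 (3.41), OAS1 (3.24), IFI44L (3.21), the macrophage lectin gene SIGLEC1 (3.15) and OASL (3.08). The 10 largest decreases were in NPIPB5, SMG1P3, NPIPB4, SMG1P1, ATP5F1P1, RAB2B, CLASP1, ERVW-1, DUTP2 and SPDYE2. NPIPB5 was 3.56-fold lower (log2 -1.83, SE 0.16, adjusted p = 0.000570) and RAB2B 2.69-fold. The NPIPB, SMG1P and SPDYE2 genes have near-identical copies, and ATP5F1P1 and DUTP2 are pseudogene symbols, so their values are uncertain. Over all genes 727 were higher and 746 lower, against 521 and 874 with the values rescaled by the median ratio. A fit of only the mutant rescue and knockdown libraries called 123 higher and 156 lower. Without mutant rescue replicate 1, 1850 were higher and 951 lower. The total of 1473 was 94, 79, 966, 2801 and 484 without knockdown replicate 1, knockdown replicate 2, rescue replicate 1, mutant rescue replicate 1 and mutant rescue replicate 2 in turn. Of the genes called lower, 380 had a mean level below 5 ppm of the linear total of a library, with a median log2 change of -0.41, and 116 of these passed an adjusted p of 0.05 in the authors' deposited table. That table had 570 genes higher and 458 lower, and all 793 genes called in both had the same direction. Cytosolic ribosomal protein genes had a median log2 change of 0.27 (camera adjusted p = 0.000129, and adjusted p = 0.768 with an estimated correlation) and mitochondrially encoded genes one of 0.40 (camera adjusted p = 0.140). With 1 library left out the medians were between 0.08 and 0.46, with 0 to 35 ribosomal protein genes called higher, and between 0.08 and 0.67.

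Immediate early genes were higher in mutant rescue than in knockdown in 6 of 25 members and lower in 0, with DUSP1 (1.34, SE 0.12), JUN (1.31, SE 0.14), FOS (0.66, SE 0.10) and MYC (0.65, SE 0.14) first. Of 44 nuclear-encoded oxidative phosphorylation genes 4 rose, CYC1 (0.50), ATP5C1 (0.43), SDHB (0.47) and NDUFV1 (0.36). Adjusted over the list alone, 12 immediate early genes rose, and of the oxidative phosphorylation genes 16 rose and 1 fell, NDUFS1 (-0.31, named after its value was seen). Camera called both (adjusted p = 0.00293 and 8.2e-05), with adjusted p = 0.715 and 0.749 with an estimated correlation. Without knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn, the members called were 2, 2, 6, 6, 10 and 4 for immediate early and 0, 0, 0, 0, 18 and 0 for oxidative phosphorylation genes, and NDUFV1 did not pass in the authors' deposited table.

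Rescue was compared directly with mutant rescue to ask which transcripts differed between the intact and the mutant protein. Interferon-stimulated genes were higher in rescue in 37 of 38 members, with a median log2 difference of 1.74, among them IFIT3 (2.59, SE 0.12), RSAD2 (2.51, SE 0.11) and USP18 (2.47, SE 0.11). S phase genes were higher in rescue in 20 of 47 members and lower in 0, led by the chromatin remodeller gene HELLS (1.22, SE 0.15), MCM7 (0.63, SE 0.08), the exonuclease gene EXO1 (0.86, SE 0.14) and MCM5 (0.53, SE 0.09). Monocyte genes were lower in rescue in 8 of 26 members and higher in 0, led by LYZ (-1.42, SE 0.22), CST3 (-0.77, SE 0.12), S100A8 (-0.68, SE 0.12) and FCER1G (-0.64, SE 0.13). When adjusted over the list alone, 38 interferon-stimulated genes were higher, 28 S phase genes were higher and 1 lower, E2F1 (-0.41, named after its value was seen), and 10 monocyte genes were lower. Camera called the 3 lists at adjusted p = 1.57e-44, 8.22e-12 and 0.00103. The first and second held with an estimated correlation (adjusted p = 0.0332 for each), while monocyte genes had adjusted p = 0.179 with an estimated correlation. Without knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2 and mutant rescue replicate 2 in turn, the members called were 8, 8, 7, 2 and 11 for S phase and 3, 3, 4, 1 and 3 for monocyte genes. Interferon-stimulated genes called stayed between 33 and 37 in the fits that left out 1 library.

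The 10 genes most increased in rescue over mutant rescue were IFITM1, CXCL10, NEXN, LGALS3BP, OAS3, IFIT3, RSAD2, ISG20, IFITM3 and USP18. IFITM1 was 8.78-fold higher (log2 3.13, SE 0.13, adjusted p = 2.33e-05), CXCL10 8.32-fold and the actin-binding gene NEXN 7.67-fold. The 10 most decreased were PCSK5, MCEMP1, C1orf56, ZNF33B, LYZ, C3, RGS16, FCGRT, PLEC and VASH1. PCSK5 was 3.43-fold lower (log2 -1.78, SE 0.31, adjusted p = 0.0114), MCEMP1 3.13-fold and the complement gene C3 2.60-fold. C1orf56 did not pass in the authors' deposited table (adjusted p = 0.0858). Over all genes 769 were higher and 601 lower, and the total of 1370 was 590, 587, 676, 241, 2870 and 695 without knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn. The larger share turned without mutant rescue replicate 1, with 1184 higher and 1686 lower. A fit of only the rescue and mutant rescue libraries called 147 higher and 45 lower in rescue. Of the 769 genes called higher, 195 had a mean level below 5 ppm of the linear total of a library, and of the 601 called lower 84. The authors' deposited table had 518 genes higher and 484 lower in mutant rescue than in rescue, and all 820 genes called in both had the same direction.

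Of 24 NF-kB and inflammatory genes 11 were higher in rescue, including NFKBIA (1.39, SE 0.11), IL1RN (1.10, SE 0.10) and CCL2 (0.96, SE 0.12), and 2 were lower, IL1B (-0.29) and PLAUR (-0.45), both named after their values were seen. Neither of these lower calls held without knockdown replicate 1 or without mutant rescue replicate 2. In the HOXA/MEIS1 program 4 of 18 genes were higher, ZEB2 (0.99, SE 0.12), JMJD1C (0.63), SATB1 (0.47) and HOXA9 (0.39). Of 56 G2/M genes 7 were higher, BUB1 (0.64), TMPO (0.71) and CENPF (0.44) among them. Adjusted over the list alone, 12 NF-kB genes were higher and 4 lower, with CXCL2 (-0.22) and TNFAIP2 (-0.36) added, 4 HOXA/MEIS1 genes higher, and 10 G2/M genes higher and 1 lower, PSRC1 (-0.48), and these 3 genes were also named after their values were seen. Camera called the 3 lists at adjusted p = 0.000358, 0.0147 and 0.00116, with adjusted p = 0.107, 0.179 and 0.135 with an estimated correlation. The NF-kB list, which includes CXCL10, had a median log2 difference of 0.30 and a mean of 0.48. Without knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn, the members called higher were 9, 9, 7, 7, 11 and 9 for NF-kB, 2, 2, 2, 1, 6 and 3 for HOXA/MEIS1 and 1, 1, 1, 0, 11 and 2 for G2/M genes. SATB1, HOXA9 and CENPF did not pass in the authors' deposited table.

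Transcript classes that can follow RNA quality also differed between the rescue arms. Of 71 cytosolic ribosomal protein genes 20 were lower in rescue, with RPLP0 (-0.90, SE 0.11) and RPL12 (-0.93, SE 0.17) first, and the list averaged 11.89 and 11.72 in the rescue libraries and 12.12 and 12.51 in the mutant rescue libraries. Of 13 mitochondrially encoded genes 5 were lower, MT-CO1 (-1.24, SE 0.22), MT-ND4 (-0.76), MT-ND2 (-1.02), MT-ND5 (-0.86) and, named after its value was seen, MT-CO3 (-0.72), and the list averaged 11.65 and 11.74 in rescue and 12.16 and 12.65 in mutant rescue. Of 12 replication-dependent histone genes 4 were lower, HIST1H4C (-0.68), HIST1H3H (-0.61), HIST1H4E (-0.45) and HIST1H2AG (-0.47). When adjusted over the list alone, 56 ribosomal protein, 10 mitochondrially encoded and 5 histone genes were lower, HIST1H2BJ (-0.16, named after its value was seen) the fifth of them. Camera called the 3 lists at adjusted p = 3.75e-16, 8.67e-06 and 0.00170, with adjusted p = 0.515, 0.515 and 0.135 with an estimated correlation. Without control replicate 1, knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn, the members called were 16, 2, 2, 3, 1, 56 and 3 for ribosomal proteins, 6, 1, 1, 0, 0, 8 and 1 for mitochondrially encoded genes and 2, 2, 2, 1, 0, 4 and 3 for histones, and the medians of the first and second list lay between -0.65 and -0.30 and between -0.98 and -0.46. HIST1H2AG did not pass in the authors' deposited table. Camera also called nuclear-encoded oxidative phosphorylation genes lower in rescue (median log2 difference -0.27, between -0.35 and -0.17 with 1 library left out, adjusted p = 5.12e-05, and 0.515 with an estimated correlation). Of its 44 members 1 was called, NDUFB5 (-0.38, SE 0.10), which did not pass in the authors' deposited table, and 0 were called when adjusted over the list alone. With mutant rescue replicate 1 left out 13 were lower and 1 higher, and with any other library left out 0 were called.

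Knockdown against control and rescue against mutant rescue share no library, so their calls were set against each other. They do share the variance estimate of each gene, which can place the same genes in both lists. Fisher's exact test also takes genes as independent, so its p-values here may be far too small. Of the genes called higher in knockdown, 193 were lower in rescue than in mutant rescue, where independent lists would share 32.1 (one-sided Fisher's exact p = 4.03e-103). Of those called lower in knockdown, 143 were higher in rescue, where independent lists would share 57.2 (one-sided Fisher's exact p = 7.32e-26). In the same direction 47 genes were higher in both, against 41.1 (one-sided Fisher's exact p = 0.186), and 7 lower in both, against 44.7. The 10 of these genes whose larger adjusted p of the contrasts was smallest were RNF130, FCGRT, LGALS3, MCEMP1, GRN, C1orf162, VASH1, VSIG4, QPCT and PLD3, each higher in knockdown and lower in rescue than in mutant rescue. RNF130 changed by 1.25 and -1.06, the Fc receptor gene FCGRT by 1.36 and -1.29, the galectin gene LGALS3 by 1.08 and -1.16, and GRN, which encodes progranulin, by 1.26 and -0.88. Across the 13030 genes, which are not independent replicates, the log2 changes had a Pearson r of -0.21 and a Spearman rho of -0.18. The 336 genes called in opposite directions became 175, 183, 49, 57, 120, 55, 563 and 222 without control replicate 1, control replicate 2, knockdown replicate 1, knockdown replicate 2, rescue replicate 1, rescue replicate 2, mutant rescue replicate 1 and mutant rescue replicate 2 in turn. The part higher in knockdown went from 193 to 107, 115, 46, 47, 82, 41, 306 and 159 in that order, with a largest one-sided Fisher's exact p of 1.18e-37. The part lower in knockdown went from 143 to 68, 68, 3, 10, 38, 14, 257 and 63. Its 3 genes without knockdown replicate 1 stood against 2.09 for independent lists (one-sided Fisher's exact p = 0.347), and its 14 without rescue replicate 2 against 10.1 (one-sided Fisher's exact p = 0.131). Fitting only the groups compared left 12 genes of this part against 16.2, and 30 of the part higher in knockdown against 4.075. Pearson's r was -0.135 without control replicate 1, -0.141 without rescue replicate 1 and -0.0974 with the fold changes of the authors' deposited table.

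**Figure D3:**
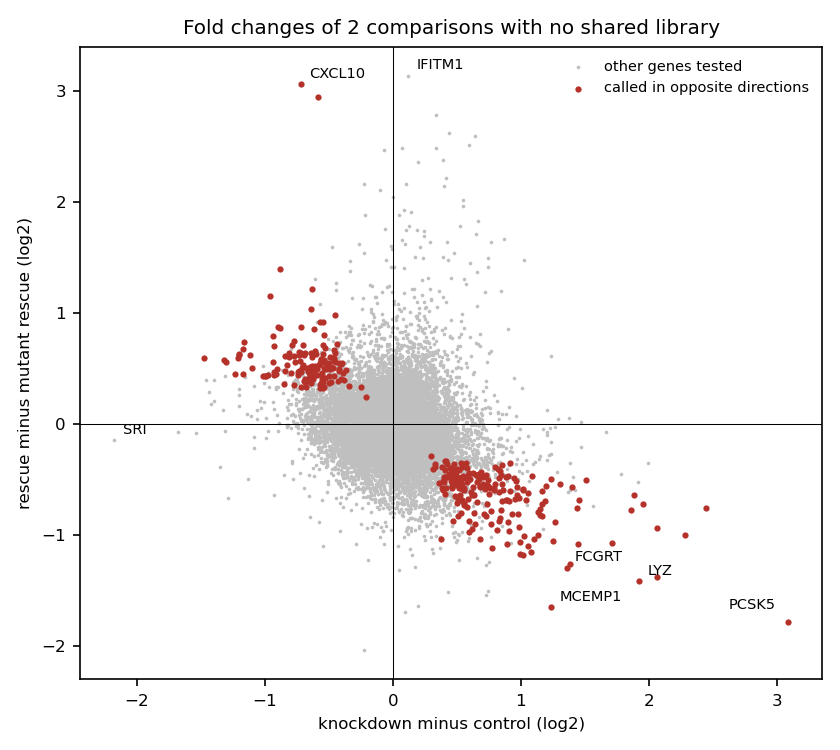
Log2 fold changes of knockdown over control (x axis) against rescue over mutant rescue (y axis) for the 13030 genes tested; red points are the 336 genes called in opposite directions and gray points the others. PCSK5 lies at 3.09 and -1.78, and LYZ at 1.92 and -1.42.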

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

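The calls of the authors' deposited table, the counts of list members without each library and the use of ppm in the filter were chosen only after the data were seen. None of 333 called values for single genes changed sign under any alternative run, and 10 of 25 that were not called did, among them MFSD2A in rescue against mutant rescue (0.1327, and -0.002628 without mutant rescue replicate 2). This was largely fixed in advance, since most settings leave a log2 change as it is. Genes named for the largest changes had libraries that do not overlap between groups, so leaving out 1 library cannot turn their sign. The lack of sign changes is thus no evidence of stability. The direction with more called genes turned for knockdown against control (697 higher, 970 lower) with the 2-fold threshold (81, 44) and without control replicate 2 (255, 237), knockdown replicate 1 (116, 71) and knockdown replicate 2 (101, 78). For mutant rescue against knockdown (727, 746) it turned in 9 settings, and without mutant rescue replicate 1 the counts were 1850 and 951. For rescue against mutant rescue (769, 601) it turned without mutant rescue replicate 1 (1184, 1686) and in the authors' deposited table (484, 518). Fitting only the libraries of the groups compared gave 2620 calls for knockdown against control, 1246 for rescue against knockdown, 279 for mutant rescue against knockdown, 192 for rescue against mutant rescue and 42 oppositely called genes. The cause was not tested. The single fit shares each gene's variance over groups with unlike replicate SDs of the log2 difference (0.148 in knockdown, 0.303 in mutant rescue). Its calls that involve mutant rescue may therefore be too many. Asking also for a 2-fold change left 125, 143, 115 and 159 calls and 15 oppositely called genes, by construction. The authors' deposited table gave 2615 calls for knockdown against control, 1319 for rescue against knockdown and a correlation of the fold changes of -0.09735, and the cause was not tested. With an estimated correlation, camera called 2, 2, 1 and 2 lists in the order of the contrasts, against 11, 14, 6 and 10 with the preset one. Fry called 11, 14, 5 and 9. Leaving out 1 library gave 179 to 2359 calls for knockdown against control, 176 to 864 for rescue against knockdown, 79 to 2801 for mutant rescue against knockdown, 241 to 2870 for rescue against mutant rescue, 49 to 563 oppositely called genes and correlations of -0.276 to -0.1351, with fewer libraries behind each estimate. The replicate block gave 1787, 592, 1805 and 1765 calls and 403 oppositely called genes. Deviations of same-numbered libraries correlated at 0.41 between knockdown and rescue and at -0.02 to 0.19 in the other pairs of groups. The labels give no shared day or batch, so the main fit did not pair the samples by number. An effect shared by same-numbered libraries of knockdown and rescue is not excluded. Without the trend, with rescaling, without the filter and with the stricter filter, the totals of called genes stayed within 1.5 times those reported. By direction they did not: for mutant rescue against knockdown the stricter filter gave 389 lower and no filter 469 higher. Of 44 counts of list members, 5, 3, 8 and 1 went beyond 1.5 times in these settings. Of 358 values for single genes, 215 lost their call with the 2-fold threshold, 90 with only the groups compared, 30 in the authors' deposited table, where 1 was gained, 30 without the filter, 24 without the trend, 10 with rescaling and 3 with the block. Leaving out knockdown replicate 1 or 2 ended 171 and 169 of them. Pseudocounts and transcript-level values were not run, since the table holds log2 values per gene. Depth limits are unknown without counts.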

Other observations

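Chosen only after the result was seen were the tests of a return to the control level, of an equal step shared by the rescue arms, of a shared vector or selection step, of mutant rescue replicate 2 in each direction, of the IGF2BP2 level in mutant rescue, and of the genes that stayed near the knockdown level; the exact interval asked of the interferon test was added after its value was seen, as were the condition that no excess beyond chance remain without mutant rescue replicate 2 and the condition that the hairpin test hold without each library.

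Other gene groups of the fixed lists moved gene by gene in knockdown. Among granule genes, the growth factor receptor gene CSF3R (1.11, SE 0.11) and the regulator gene CEBPE (0.86, SE 0.11) rose, while the protease genes CTSG (-0.82, SE 0.12) and PRTN3 (-0.78, SE 0.14) fell; the list's camera adjusted p was 0.892. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.91 (SE 0.10), with camera adjusted p = 0.153 for p53 targets. Of 18 lipid handling genes 3 rose, CD36 (1.91, SE 0.15), MBOAT7 (0.75, SE 0.11) and MFSD2A (0.49, SE 0.13), and 3 fell, FABP5 (-0.74, SE 0.11), FADS2 (-0.68, SE 0.13) and, named after its value was seen, FADS1 (-0.49, SE 0.09). Of 31 glycolysis and hypoxia genes 2 rose, HK2 (0.77, SE 0.14) and BNIP3L (0.52, SE 0.09), and 6 fell, with P4HA1 (-1.003, SE 0.118) and LDHA (-0.66, SE 0.10) first. Of 23 cholesterol synthesis genes 1 rose, MSMO1 (0.80, SE 0.09), and 2 fell, HMGCS1 (-0.73, SE 0.10) and FDPS (-0.46, SE 0.11). Camera called none of lipid handling (adjusted p = 0.892), cholesterol synthesis (0.435) and glycolysis (0.435). Fewer members of each of these lists were called without knockdown replicate 1. The glutamine transporter gene SLC38A1 fell by 1.11 (SE 0.11; list adjusted p = 0.132), and the m6A reader gene YTHDF2 changed by -0.42 (SE 0.11, list adjusted p = 0.0723). Camera called amino acid response, protein stress and oxidative phosphorylation genes lower (adjusted p = 0.0154, 0.0191 and 4.97e-07), with adjusted p = 0.537, 0.494 and 0.582 with an estimated correlation. SOCS2, of the leukemia stem cell score, had a change of -0.27 (adjusted p = 0.0948, list 0.892), and passed in the authors' deposited table. The IGF2BP family (0.435), the genes of the series title (0.153), apoptosis (0.620), NF-kB (0.579), immediate early (0.579), histone (0.579) and T and NK cell genes (0.892) were not called by camera either.

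In rescue, WARS, an aminoacyl-tRNA synthetase gene that interferon is known to induce, rose by 1.12 (SE 0.10) over knockdown, PMAIP1 by 0.92 (SE 0.12) and ACSL1 by 0.97 (SE 0.13). Camera called arginine methyltransferase (adjusted p = 0.000933), MYC target (0.000295), HOXA/MEIS1 (0.0106), immediate early (0.00913), amino acid response (0.00361), glutamine (0.0261) and series title genes (0.0383) higher. None of these held, at adjusted p = 0.146, 0.146, 0.146, 0.404, 0.404, 0.290 and 0.404 with an estimated correlation. In mutant rescue over knockdown BAX rose by 0.84 (SE 0.12) and PDK1 changed by -0.87 (SE 0.15), and camera called granule and protein stress genes higher (adjusted p = 0.0210 and 0.0209, and adjusted p = 0.715 for each with an estimated correlation). Of the lists for other cell types, 5 of 14 T and NK cell genes, 2 of 10 B cell genes, 2 of 16 erythroid and megakaryocyte genes and 2 of 14 packaging cell and stroma genes passed the filter. Their highest members were NCAM1 at a mean log2 value of 9.96, BLNK at 4.91, EPOR at 9.47 and KRT18 at 6.12.

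Interferon-stimulated genes were higher in both rescue arms than in knockdown. A return to the control state is argued against, since the median over the list was 3.765 above control in rescue, with 38 of 38 genes above it. An equal response of both arms to a shared step, as the whole cause, is argued against by a median of 1.742 between rescue and mutant rescue. A vector or selection step shared by both arms may be part of the cause, or all of it if it acted unequally on the arms. Mutant rescue lay a median of 1.78 above knockdown, and the labels name no knockdown arm given an empty vector. Such a step and an effect of either protein therefore cannot be told apart. An effect of IGF2BP2 or of its mutant stays open as a hypothesis.

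Genes changed in knockdown were often called the other way between rescue and mutant rescue. Mutant rescue replicate 2 as the only source is argued against for those higher in knockdown, as 159 were found without it where independent lists would share 20.9. For those lower in knockdown it stays open: 63 were found against 44.0, a ratio of 1.431 (one-sided Fisher's exact p = 0.00214), within the bound of 1.5 but with an excess left, and the ratio was also under 1.5 without knockdown replicate 1 (1.438), rescue replicate 1 (1.418) and rescue replicate 2 (1.393). The interferon response of the rescue arms stays open: in 38.01% of 563 genes called without mutant rescue replicate 1, that library differed from knockdown in the direction in which rescue differed from mutant rescue, with an exact 95% interval of 33.98% to 42.16% around the bound of 40% set beforehand. The knockdown libraries entered both the choice of these genes and this share, so its value with no change is unknown. Genes are not independent, so the interval may be too narrow. A lower IGF2BP2 transcript in the mutant arm may contribute, with a log2 difference of 0.3938 (adjusted p = 0.0839), and cannot be told apart from an effect of the mutation. Loss of a function of IGF2BP2 through the mutation remains a hypothesis that no test here isolates.

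Of the 44 genes at least 2-fold lower in knockdown, loss through the hairpin itself stays open. Of them 31.82% were called higher in rescue than in mutant rescue, against 13.93% of the 926 other genes called lower (one-sided Fisher's exact p = 0.00261), which met the bound set beforehand. Of the 8 fits that left out 1 library, 7 called any of the other genes, 4 of these kept a share at least 1.5 times that of the other genes, and 2 met the whole bound, without control replicate 1 (21.74% and 9.949%) and without mutant rescue replicate 1 (38.64% and 18.55%, one-sided Fisher's exact p = 0.00182). Fewer calls may account for part of the loss in the others. Without mutant rescue replicate 2 the shares were 9.091% and 4.552% (one-sided Fisher's exact p = 0.148), and the test rests on genes lower in knockdown, for which that library as the only source stays open. For 23 of the 44, which lay within 0.5 of knockdown in rescue and were not called higher than in mutant rescue, it cannot be told apart from incomplete restoration, since the hairpin sequence was not used here. They include SRI, which averaged 10.45 in control, 8.27 in knockdown and 8.55 in rescue, and VAMP8, at 12.03, 10.50 and 10.79. A dependence of these transcripts on IGF2BP2 stays open as well.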
